A study of Mus musculus with 14 samples.

How the data were processed

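Gene expression was measured by RNA sequencing of 14 libraries from mouse blood-forming cells. Fetal liver RNA was taken up in Trizol and LK RNA with a column kit, and libraries were made with a stranded total RNA kit, with Ribo-Zero removal of ribosomal RNA named for the fetal liver samples, per the labels' protocols. Reads were aligned with STAR 2.5.3 and quantified with RSEM against GRCm38 (mm10), per the submitters' processing notes. The RSEM version and the annotation release are not given in the sources used here. The deposited unit is the RSEM expected count per gene, for 45706 genes, of which 45143 had an identifier in GENCODE M21. That release gave gene types, coordinates on GRCm38, and the length and GC content of the longest annotated transcript of each gene. Length was available for 99.5% of tested genes. No data column was left unassigned. In 123 cases a symbol was shared by more than 1 identifier.

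Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F tests, TMM normalisation, filterByExpr). The 8 fetal libraries formed 1 model with a mean per group, and the 6 LK libraries another, since the tissues and RNA kits differ. The filter left 15566 fetal and 13771 LK genes. P-values were adjusted by Benjamini and Hochberg within each comparison and called under 0.05. The 6 comparisons were KO against WT in LK, Ter119neg and Ter119pos, the difference of the KO effect between Ter119pos and Ter119neg, and Ter119pos against Ter119neg in WT and in KO. CPM values are TMM-normalised, and floors cover counting error only. The SE of an edgeR log2 fold change is its absolute value divided by the root of the F statistic. It therefore includes the spread between libraries. For genes at 0 in a group the fold is a lower bound from 3 counts over the group.

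Gene lists, 33 in number, were written from general knowledge before the data were examined, together with the comparisons, the alternatives and the rule for named genes. The rule named Prmt5 and, per direction, the 8 called genes with the largest log2 fold change among those with a mean of at least 5 CPM over the libraries compared and every library of 1 group above every library of the other, leaving out unnamed gene models and symbols ending in -ps. For the interaction it took 5 per direction without the condition on separated libraries. It also allowed up to 4 members with the smallest p from each list, called or not, and any member of the arginine methyltransferase, TIP60 and sex-linked lists. Some genes that the rule picks are not reported here. Lists with at least 5 tested members were tested with camera (limma 3.58.1, correlation preset at 0.01, log2 CPM with a prior count of 2), again with a correlation estimated from the data, and with fry. Members were also adjusted over the list alone.

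Whether replicate letters or mice pair libraries was checked from correlations of deviations from group means. LK libraries of the same letter had r of 0.604, 0.719 and 0.73, against -0.027 at most between letters. Deviations sum to 0 within a group, so positive values within letters push those between letters below 0. The values between letters are thus no separate evidence of pairing. Given the values within letters, results with the letter as a block stand beside the LK results where they change a call or move a count by over 1.5 times. The labels do not say what the letters share. Fetal letters had r of 0.0047 and -0.029. Libraries from mouse 1 had r of 0.155 and from mouse 4 -0.068. With 2 libraries per group the deviations mirror each other. The value for mouse 1 is thus also that for mouse 2, and that for mouse 4 also that between mice 3 and 5. The mouse 4 value therefore cannot check whether libraries of the same mouse pair. A mouse block was fitted for comparisons across fractions, in which WT rests on mouse 4 alone. A random mouse effect in limma-voom had a consensus correlation of 0.166.

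Alternatives were RLE normalisation, no low count filter, DESeq2 1.42.0, limma-voom, globin genes removed, models of 1 fraction alone, the blocks and each library left out. Where a group keeps 1 library, that library is assumed to vary like the other groups. Alternatives added after the data were seen were normalisation over protein-coding genes, removal of a per-library trend (lowess, span 0.3) on transcript length or GC content, length removal with a block, and leaving out both letter B or both letter C LK libraries.

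Total counts ranged from 19514550 to 30976961 per library. On simulated counts with 200 changed genes, the LK comparison (13612 genes) recovered 0 of 100 genes changed 2-fold and 47 of 100 changed 4-fold, with 3 calls among unchanged genes. For Ter119neg (15015 genes) these were 61, 85 and 21, and for Ter119pos (15154 genes) 59, 71 and 13. Simulated libraries were drawn independently and fitted without a letter or mouse block. Splicing was left out because gene-level counts do not show it. Reads of near-identical genes (H2-Q, Hba-a1 and Hba-a2, Csf2rb and Csf2rb2, histones, U3 copies, Rn7s1 and Rn7s2) are shared by the quantification in a way the tables do not show.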

Results

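RNA sequencing was used to follow gene expression after deletion of Prmt5, the gene for a type II protein arginine methyltransferase that places symmetric dimethylarginine on histones and splicing proteins, in mouse blood-forming cells. The deposited values are gene-level counts, so transcript levels could be compared and splicing could not. The 14 libraries fell into 6 groups. Fetal liver cells of stage E14.5 were sorted into Ter119neg and Ter119pos fractions, Ter119 being a surface antigen of maturing erythroid cells, from Prmt5 floxed mice with (KO) or without (WT) Vav-cre, a recombinase active across the blood system. Each of these 4 groups held 2 libraries from 2 mice. Mice 1 and 2 (KO) and mouse 4 (WT) gave both fractions, while mouse 3 gave the Ter119neg WT library A and mouse 5 the Ter119pos WT library A. LK cells, a sorted progenitor population, were taken from Prmt5 floxed mice with (KO) or without (WT) Mx1-cre, a recombinase that interferon switches on. Both groups had received poly(I:C), 7 days before collection, and each held 3 libraries. The labels name no mice for the LK libraries, so p-values there measure the spread between these libraries. Total counts per library ranged from 19514550 to 30976961 in LK, from 22381074 to 27620734 in Ter119neg and from 19880052 to 29652947 in Ter119pos.

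Prmt5 (ENSMUSG00000023110, chromosome 14, 54507187 to 54517525, minus strand, protein coding) was lower in every KO library than in every WT library of the same population. In LK cells its normalised level was 11.5 ± 0.903 CPM (SD, n = 3) in KO and 81 ± 25.5 in WT, a log2 fold change of -2.81 (SE 0.28, edgeR adjusted p = 0.00669; -2.78 and 0.000591 with the letter A, B or C as a block). In Ter119neg cells the level was 4.38 ± 0.179 against 52 ± 0.347 CPM (SD, n = 2 each; log2 fold change -3.57, SE 0.149, adjusted p = 1.45e-07). In Ter119pos cells it was 4.28 ± 0.903 against 15.7 ± 2.79 CPM (n = 2 each; log2 fold change -1.89, SE 0.177, adjusted p = 2.31e-06). Reads from exons outside the floxed segment still count toward the gene, so the remaining CPM does not measure the share of undeleted cells. In LK the adjusted p was 0.0715, 0.0531 and 0.0611 without KO library A, B or C respectively, and 0.0965 without both letter C libraries, while the log2 fold change stayed between -2.97 and -2.48 across all alternatives.

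**Figure D1:**
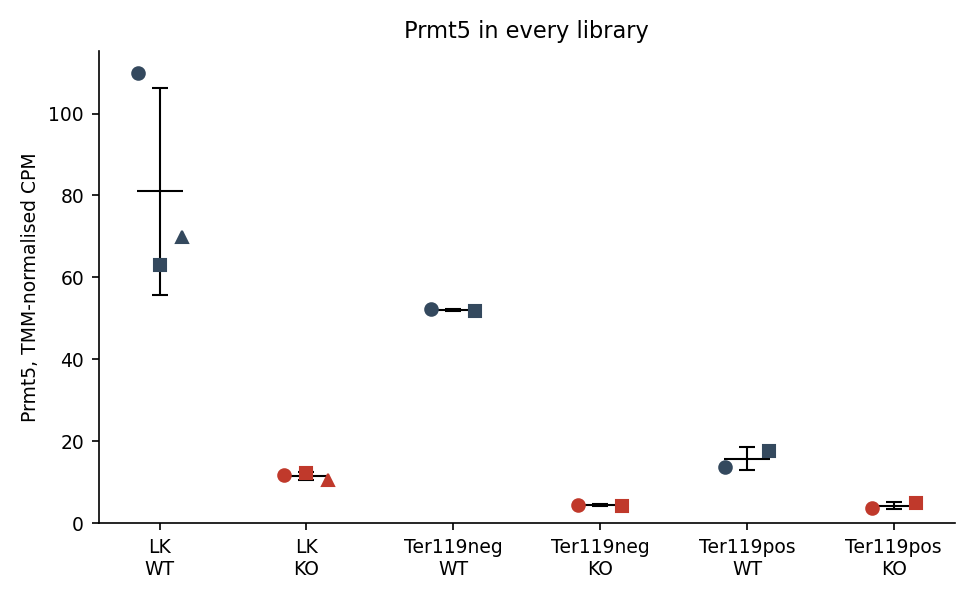
Prmt5 level (TMM-normalised CPM, y axis starting at 0) in each of the 14 libraries, by population and genotype. Points are libraries with circles, squares and triangles for letters A, B and C, bars are group means and error bars are 1 SD. The highest KO library, at 12.3 CPM, lies below the lowest WT library, at 13.8 CPM.

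The comparison of KO with WT LK cells asked how loss of Prmt5 changes expression in adult progenitors after acute deletion. Genes induced by the tumour suppressor p53 were higher in KO cells, with 18 of 40 measured targets called higher and none lower. Zmat3, a p53-induced RNA-binding protein, reached 218 ± 25.2 CPM in KO against 5.34 ± 0.624 in WT. Eda2r, a member of the tumour necrosis factor receptor family, reached 22.9 ± 4.71 against 0.298 ± 0.0952 CPM. Called lower were 2 of 25 granulocyte and monocyte genes and 3 of 13 mast cell, basophil and eosinophil genes. Both lists passed camera, and neither did with an estimated correlation (adjusted p = 0.555 and 0.562). Of 13771 genes tested, 250 were called at an adjusted p under 0.05, 159 higher and 91 lower in KO.

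Among the genes picked by the naming rule, the highest log2 fold changes were those of Zfp365 (8.55, SE 0.545; chromosome 10, 67886103 to 67912662), Ahnak2 (8.49), Plk2 (7.23, a polo-like kinase), Fat1 (6.57, an atypical cadherin), Tnfsf4 (6.45, the ligand of OX40), Fam212b (6.25), Eda2r (6.20) and Fam198b (6.04), with adjusted p values from 0.000695 to 0.00439. At the other end stood Klf4 (-3.37, SE 0.413, adjusted p = 0.0136; chromosome 4, 55527143 to 55532466), a transcription factor of monocyte differentiation. With Prmt5 set aside, the others were the class I genes H2-Q7 (-3.20), H2-Q5 (-2.76, annotated as a polymorphic pseudogene) and H2-Q6 (-2.71), the class II chain H2-Aa (-2.72), the mast cell and basophil protease Prss34 (-3.18) and the eosinophil ribonuclease Ear6 (-3.04). The H2-Q genes are near-identical copies of each other, so the split of reads between them is uncertain. In each of these genes, as the choice of named genes required, every library of 1 genotype lay above every library of the other.

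The p53 list had a median log2 fold change of 1.95, and 25 members were higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.08e-24; adjusted p = 0.0077 with an estimated correlation). Further members were Tnfrsf10b (3.43), the receptor for the death ligand TRAIL, Sesn2 (2.84), a stress-induced sestrin, and Pmaip1 (2.35), a proapoptotic BH3-only protein. With the letter A, B or C as a block, 29 members were higher and 2 lower, and the camera adjusted p was 7.96e-19, or 0.266 with an estimated correlation. Without 1 library in turn, between 9 and 21 members were higher, with 9 without WT library A, 10 without KO library A, 11 without KO library B and 10 without KO library C. Without both letter C libraries 7 were higher, and without both letter B libraries 16.

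The granulocyte and monocyte list was lower by camera (median -1.41, adjusted p = 2.11e-07; 0.555 with an estimated correlation), with 2 of 25 members called lower, Klf4 and Ly86 (-1.41), 5 when adjusted over the list alone and 19 under the letter block. Among its other members, the neutrophil granule gene Ngp stood at 8486 CPM in WT library C, 1018 in WT library B and 1577 in KO library C, against 117.2 to 157.9 CPM in the remaining 3 libraries. The mast cell, basophil and eosinophil list was also lower (median -1.66, adjusted p = 0.000752; 0.562 with an estimated correlation), with 3 of 13 members called, Ear6, Prg3 (-2.64) and Ear2 (-2.50), 7 lower and 1 higher when adjusted over the list alone and 7 lower under the block. Ear2 lost its call with the trend on transcript length removed (-2.14, adjusted p = 0.108), short transcripts as a class being lower in LK KO (median -0.48 in the shortest of 8 length bins; Spearman rho 0.344 across 12046 genes). Macrophage markers had 1 of 11 members called lower, Adgre1 (-2.07), which encodes F4/80 (camera adjusted p = 0.0386, 0.0843 under the block, 0.555 with an estimated correlation). The stem and progenitor list was higher (median 0.45, adjusted p = 0.000326; 0.555 with an estimated correlation), with Slamf1 (2.09), which encodes CD150, called of 31 members, 4 when adjusted over the list alone and 10 higher with 1 lower under the block. Of the megakaryocyte list, Selp (2.73) and Gp5 (2.01), both platelet surface proteins, were called of 16 members, and the list did not pass camera (adjusted p = 0.0879; 3 higher over the list alone and 5 under the block). Without WT library A, KO library A, KO library B or KO library C, the calls were 0, 0, 0 and 1 in the granulocyte and monocyte list, 0 each in the mast cell list and 0, 0, 1 and 0 in the megakaryocyte list. Slamf1, Adgre1 and Col1a2, a collagen gene of the endothelial and stromal list, lost their calls in each of these 4 cases and without WT library C.

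S phase and DNA replication genes (median -0.35, camera adjusted p = 0.000326, 0.578 with an estimated correlation) had 0 of 45 members called by edgeR and 13 lower under the block. G2 and mitosis genes (median -0.37, adjusted p = 0.00429, 0.786 with an estimated correlation) had 0 of 42 called and 11 lower under the block. Ribosome biogenesis genes (median 0.29, adjusted p = 0.000431, 0.587 with an estimated correlation) had 0 of 46 called and 13 higher under the block, and mitochondrially encoded genes (median -0.80, -0.55 with the length trend removed, adjusted p = 0.000386, 0.578 with an estimated correlation) 0 of 13 called and 8 lower under the block. No member of these 4 lists was called when adjusted over the list alone. The Fanconi anemia list (median -0.49, adjusted p = 0.0453, 0.555 with an estimated correlation) had 0 of 15 members called, 1 lower when adjusted over the list alone and 5 lower under the block. Homologous recombination genes did not pass camera (median -0.13, adjusted p = 0.253), with 0 of 36 called, none over the list alone and 4 lower under the block. None of the 18 genes of the TIP60 acetyltransferase complex was called (camera adjusted p = 0.842; 1 higher under the block). Of the endothelial and stromal list, Col1a2 (2.81), a collagen chain, was called of 7 members, and 3 over the list alone (camera adjusted p = 0.000578, 0.555 with an estimated correlation; 4 under the block). Under the block 3 more lists passed camera, namely lymphoid markers (adjusted p = 0.0358 against 0.113 without it), interferon response (0.0358 against 0.0526) and histone genes (0.00187 against 0.329). With an estimated correlation under the block the adjusted p was 0.74 for each of these 3. Single genes of other lists that were called were Slc4a1 (-5.31, the anion exchanger of red cells), Pycr1 (-1.90, a proline synthesis enzyme), Prpf3 (1.13, a U4/U6 spliceosomal protein) and Egr1 (3.32, an immediate early transcription factor).

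The letter block called 3129 genes in LK, 1363 higher and 1766 lower. Among these were all 250 called without it, and DESeq2 called 963, 485 higher and 478 lower. The count was 33 without WT library A, 134 without WT library C, 37, 40 and 36 without KO libraries A, B and C, 71 without both letter B libraries, in which the 18S ribosomal RNA gene Rn18s-rs5 took 18% (WT) and 23.4% (KO) of counts, and 14 without both letter C libraries. Of the 32 named genes called, 12 kept the call whichever library was left out: Zfp365, Ahnak2, Plk2, Fat1, Tnfsf4, Fam212b, Eda2r, Fam198b, Zmat3, Tnfrsf10b, Sesn2 and Egr1.

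The comparison of KO with WT Ter119neg cells asked the same in fetal liver cells before or outside the Ter119-positive erythroid stages. Genes induced by p53 were again higher, 33 of 40, with none lower, and macrophage markers were lower, 16 of 17. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose from 3.47 ± 3.09 to 52 ± 4.75 CPM, and Csf1r, the receptor of macrophage colony-stimulating factor, fell from 53.7 ± 3.07 to 16.9 ± 3.95 CPM. Of the replication, mitosis and Fanconi anemia lists, 17 of 45, 15 of 42 and 5 of 15 members were lower, and 7 to 10, 4 to 8 and 2 to 4 with 1 library left out. The p53 and macrophage lists and these 3 passed camera, and none did with an estimated correlation (adjusted p from 0.0847 to 0.632). Of 15566 genes tested, 2976 were called, 1490 higher and 1486 lower in KO.

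Among the genes picked by the naming rule, the highest log2 fold changes were those of Xist (9.08, SE 2.594, adjusted p = 0.0291), Zfp365 (4.53, SE 0.51), Eda2r (4.12), Prrg4 (3.95), Cdkn1a (3.87; SE 0.407, adjusted p = 6.88e-05), Fam198b (3.86), the T cell receptor gamma segment Tcrg-C1 (3.83) and the ubiquitin ligase gene Hecw1 (3.68). Xist, the RNA of the inactive X chromosome, stood at 371.7 CPM in the library of mouse 2, which had 0 CPM of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, and at 0.2147 to 0.9898 CPM in the other 3 libraries, so the difference rests on that mouse. Lowest of those picked were 4 copies of the U3 small nucleolar RNA with identical counts, given here as Rnu3b4 (-5.81, SE 1.014, adjusted p = 0.00195), whose reads cannot be told apart. Rnu3b4 varied widely between libraries, at 20.4 and 138 CPM in WT libraries A and B and 2.83 and 0 CPM in KO libraries A and B. With Prmt5 set aside, next came the macrophage-secreted Cd5l (-3.25, SE 0.338, adjusted p = 6.37e-05), Sdc3 (-2.69), a syndecan, and Ctss (-2.67), a lysosomal cysteine protease of antigen-presenting cells.

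The p53 list had a median log2 fold change of 1.58 (34 higher when adjusted over the list alone; camera adjusted p = 4.58e-20, 0.224 with an estimated correlation), and Psrc1 (2.92), Trp53inp1 (2.70), Ercc5 (2.43), a nuclease of excision repair, Sesn2 (2.25) and the proapoptotic Bax (1.16) were among its members. The macrophage list had a median of -2.38 (17 lower when adjusted over the list alone; adjusted p = 2.22e-14, 0.364 with an estimated correlation). Its members included C1qc (-2.97), a complement chain, the lysosomal protease Lgmn (-2.48), Adgre1 (-2.38) and Csf1r (-1.67). Granulocyte and monocyte genes were lower in 12 of 25 cases, 15 over the list alone (adjusted p = 1.93e-05, 0.705 with an estimated correlation). Csf3r stood at -1.57. Lymphoid genes were lower in 3 of 14 cases, 7 over the list alone (adjusted p = 0.00411, 0.705 with an estimated correlation). The recombinase gene Rag1 stood at -2.13, and 1 was lower without KO library A and 1 without WT library B. Interferon response genes were lower in 11 and higher in 1 of 39 cases, 12 and 1 over the list alone (adjusted p = 4.78e-05, 0.802 with an estimated correlation). Ifi204 stood at -2.37; 4 were lower without KO library A and 3 without WT library B. Megakaryocyte genes (2 higher and 1 lower of 19; adjusted p = 0.933), mast cell genes (1 and 3 of 13; 0.564) and endothelial and stromal genes (4 and 5 of 20; 0.922) did not pass camera. Endothelial genes were lower in 3 cases without KO library B or WT library A and higher in 2 without WT library B.

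S phase and DNA replication genes had 17 of 45 members lower and none higher, 20 over the list alone (median -0.27, adjusted p = 2.46e-07, 0.0847 with an estimated correlation). Among these were Pold1 (-1.10), a DNA polymerase subunit, the thymidine kinase Tk1 (-1.07) and the checkpoint mediator Clspn (-0.68). G2 and mitosis genes had 15 of 42 lower and none higher, 22 over the list alone (median -0.32, adjusted p = 9.13e-07, 0.632 with an estimated correlation). Among these were the topoisomerase Top2a (-0.83) and the proliferation antigen Mki67 (-0.76). Without 1 library in turn, 7 to 10 of the replication genes and 4 to 8 of the mitosis genes were lower, each of the 4 libraries moving both counts by over 1.5 times (replication 10, 7, 8 and 7, mitosis 7, 4, 8 and 5 without KO A, KO B, WT A and WT B). Homologous recombination genes had 7 of 36 lower and 2 higher, 8 and 2 over the list alone (median -0.20, adjusted p = 0.00218, 0.224 with an estimated correlation), with Brca2, which loads the recombinase, at -0.78 and the resolvase Gen1 at -0.74. Of these, 3 were lower without KO library B, and 0 were higher without any of the 4. Fanconi anemia genes had 5 of 15 lower, 6 over the list alone (adjusted p = 0.00411, 0.227 with an estimated correlation). Fanca stood at -0.68, and 2 were lower without KO library B and 3 without WT library A. Neither of these lists changed direction under any scaling tried.

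Globin genes had 6 of 9 members higher, 6 over the list alone (median 1.31, adjusted p = 9.89e-05, 0.453 with an estimated correlation). Levels in KO and WT were low for Hbq1b (0.594 and 0.132 CPM) and Hbb-bh1 (3.04 and 1.22 CPM). Hbb-bs, at 358 and 131 CPM, was far below its 115000 CPM in Ter119pos WT. Hbq1b stood at 2.17, the adult beta globin Hbb-bs at 1.45 and the embryonic Hbb-bh1 at 1.31, and 2 were higher without KO library B and 2 without WT library B. Heme synthesis genes had 5 of 14 higher, 6 over the list alone (adjusted p = 0.00623, 0.705 with an estimated correlation). Their member Alas2 was at 13.9 CPM in KO and 4.62 CPM in WT, against 3790 CPM in Ter119pos WT. The erythroid synthase Alas2 stood at 1.59, and 2 heme genes were higher without KO library B, WT library A or WT library B. The erythroid maturation list did not pass camera (5 higher and 3 lower of 31; adjusted p = 0.139), and its 3 lower calls became 0, 1, 1 and 0 without KO A, KO B, WT A and WT B and its 5 higher calls 3 without KO B. Stem and progenitor markers did not pass either (1 higher and 7 lower of 32; adjusted p = 0.0536). Cd34 stood at -0.75 and Slamf1 at 1.40, and 4 were lower without KO library B and 3 without WT library A. Ribosomal protein genes passed camera with 2 of 78 members higher and none over the list alone (median 0.24, adjusted p = 0.000158, 0.886 with an estimated correlation). Hepatoblast markers passed with 3 of 24 lower and none over the list alone (adjusted p = 0.00105, 0.802 with an estimated correlation). Their 3 calls became 13, 0, 0 and 9 without KO A, KO B, WT A and WT B, and the 2 ribosomal protein calls became 1, 0, 0 and 0. Among other arginine methyltransferases Prmt1 was higher (0.42), Carm1 (-0.39), Prmt3 (-0.44) and the Prmt5 cofactor Wdr77 (-0.33) were lower, and in the TIP60 complex Morf4l2 was lower (-0.51) and Mbtd1 higher (0.38). These 6 calls, with Xist and Hbb-bs, were the ones among 47 named genes that ended when some library was left out. Further called genes were Ddit4 (3.08), a stress-induced inhibitor of mTORC1, and Prpf3 (0.97).

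The count of called genes was 1788, 1450, 1580 and 1545 without KO library A, KO library B, WT library A and WT library B respectively. Across all alternatives 42.4 to 50.6% of called genes were higher. The share of counts taken by the structural RNAs Rn7s1, Rn7s2, Rn7sk, Rpph1 and Rmrp was 29.5 ± 2.69% in KO and 20 ± 4.67% in WT (SD, n = 2 each).

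The comparison of KO with WT Ter119pos cells asked how maturing erythroid cells differ without Prmt5. The differences were broad, with 8430 of 15566 genes called, 3864 higher and 4566 lower. Lower were 40 of 42 mitosis genes, 33 of 45 replication genes, 28 of 36 homologous recombination genes and 22 of 31 erythroid maturation genes. Higher were 31 of 40 p53 targets, 78 of 78 ribosomal protein genes, 49 of 51 histone genes and 9 of 15 immediate early and heat shock genes. These 8 lists passed camera (adjusted p from 2.61e-24 to 0.00633), and none did with an estimated correlation (0.0749 to 0.538). Cdkn1a rose from 1.37 ± 0.105 to 286 ± 41.4 CPM, while Aqp1, a water channel of the red cell membrane, fell from 74.2 ± 16.9 to 6.14 ± 2.54 CPM.

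Anxa8, an annexin, was at 0 in both WT libraries and at 24.5 ± 4.53 CPM in KO, at least 274-fold higher against the floor of 3 counts over the WT group. High log2 fold changes were also those of the costimulatory ligand Cd80 (8.42, SE 0.792, adjusted p = 2.42e-06), the neuronal tubulin Tubb3 (7.88), Cdkn1a (7.70), the neuropeptide precursor Vgf (7.54), Eda2r (7.43) and Plk2 (6.66). The histone gene Hist2h3c1 was at 0 in both KO libraries and at 10.2 ± 3.38 CPM in WT, at least 88-fold lower in KO, but it has near-identical copies that can take its reads. Other low values were those of Angpt2 (-4.05, SE 0.376, adjusted p = 2.17e-06), an angiopoietin, the DNA sensor Aim2 (-3.93), the peptide transporter Slc15a2 (-3.83), the adhesion gene Cadm3 (-3.71, at 7.47 ± 0.321 against 98 ± 15.7 CPM) and Aqp1 (-3.62).

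The p53 list had 31 of 40 members higher and 2 lower, 33 and 2 over the list alone (median 2.30, adjusted p = 3.95e-10, 0.293 with an estimated correlation), including the cyclin gene Ccng1 (4.07), Sesn2 (3.82) and Bax (2.28). G2 and mitosis genes had 40 of 42 lower and none higher, 40 over the list alone (median -1.25, adjusted p = 3.38e-13, 0.293 with an estimated correlation), including the kinetochore genes Cenpf (-2.60) and Cenpe (-2.37). Homologous recombination genes had 28 of 36 lower and 3 higher, the same counts over the list alone (median -0.89, adjusted p = 2e-06, 0.0749 with an estimated correlation). Gen1 stood at -2.12, Brca2 at -2.09 and Brca1, which acts with it in strand invasion, at -1.88. S phase and DNA replication genes had 33 of 45 lower and 2 higher, the same over the list alone (median -0.66, adjusted p = 7.84e-06, 0.0749 with an estimated correlation). Clspn stood at -2.37 and Pola1, the polymerase alpha subunit, at -1.63. Fanconi anemia genes had 10 of 15 lower, 10 over the list alone (adjusted p = 0.00413, 0.279 with an estimated correlation). Fancm stood at -1.51. The TIP60 complex did not pass camera (7 lower and 2 higher of 18, the same over the list alone; adjusted p = 0.127). Brd8 stood at -1.91, Epc2 at -1.61, Ep400 at -1.39 and Epc1 at -1.18. SR proteins and hnRNPs, which bind pre-mRNA, had 24 of 32 lower and 2 higher, the same over the list alone (adjusted p = 9.87e-05, 0.293 with an estimated correlation). Hnrnpm stood at -1.42.

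Erythroid maturation genes had 22 of 31 lower and 1 higher, the same over the list alone (median -1.05, adjusted p = 6.57e-06, 0.469 with an estimated correlation). Aqp1 was among those lower. Of 9 globin genes 3 were higher and none lower, and these were the embryonic Hbb-bh1 (3.15, SE 0.212), Hbb-y (2.90, SE 0.403) and Hba-x (2.45, SE 0.305), while the adult Hbb-bt, at 93500 ± 15900 against 70300 ± 613 CPM, was not called (0.41, adjusted p = 0.293). The globin list did not pass camera (adjusted p = 0.122). Once the transcript length trend was removed its median of 0.39 became -0.31, with 3 members higher and 2 lower, and Hbb-bh1, Hbb-y and Hba-x stood at 2.43, 2.19 and 1.88 and Hbb-bt at -0.23 (adjusted p = 0.494). Ribosomal protein genes had 78 of 78 higher, 78 over the list alone (median 2.01, adjusted p = 2.61e-24, 0.469 with an estimated correlation). Rps14 stood at 3.34. Replication-dependent histone genes had 49 of 51 higher and 2 lower, the same over the list alone (median 2.07, adjusted p = 2.73e-12, 0.538 with an estimated correlation). Hist1h3g stood at 2.48, and many of these genes are near copies of each other; Hist2h3c1 lies below the median at its bound as at its fitted value. Histone, ribosomal protein and embryonic globin transcripts are short, and short transcripts as a class were higher in KO: the median log2 fold change was 0.86 in the shortest and -0.40 in the longest of 8 length bins (Spearman rho -0.286 across 12816 genes). Structural RNAs took 35.2 ± 0.919% of counts in KO and 6.14 ± 0.0849% in WT (SD, n = 2 each).

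**Figure D2:**
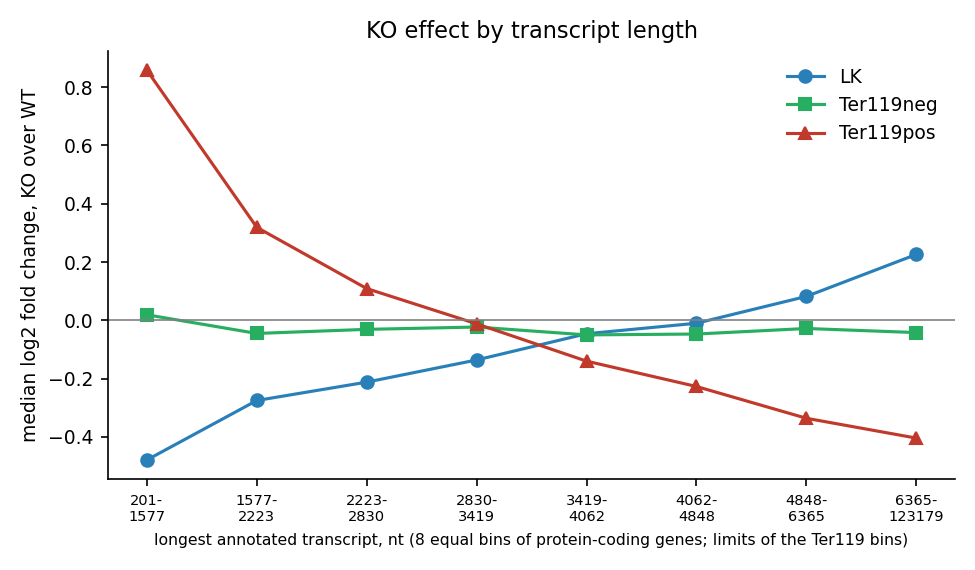
Median log2 fold change of KO over WT (y axis) of protein-coding genes in 8 bins of longest annotated transcript (x axis, nucleotides), for LK (circles), Ter119neg (squares) and Ter119pos (triangles). From the shortest to the longest bin the median goes from 0.86 to -0.40 in Ter119pos and from -0.48 to 0.23 in LK, and in Ter119neg it stays between -0.05 and 0.02.

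**Figure D3:**
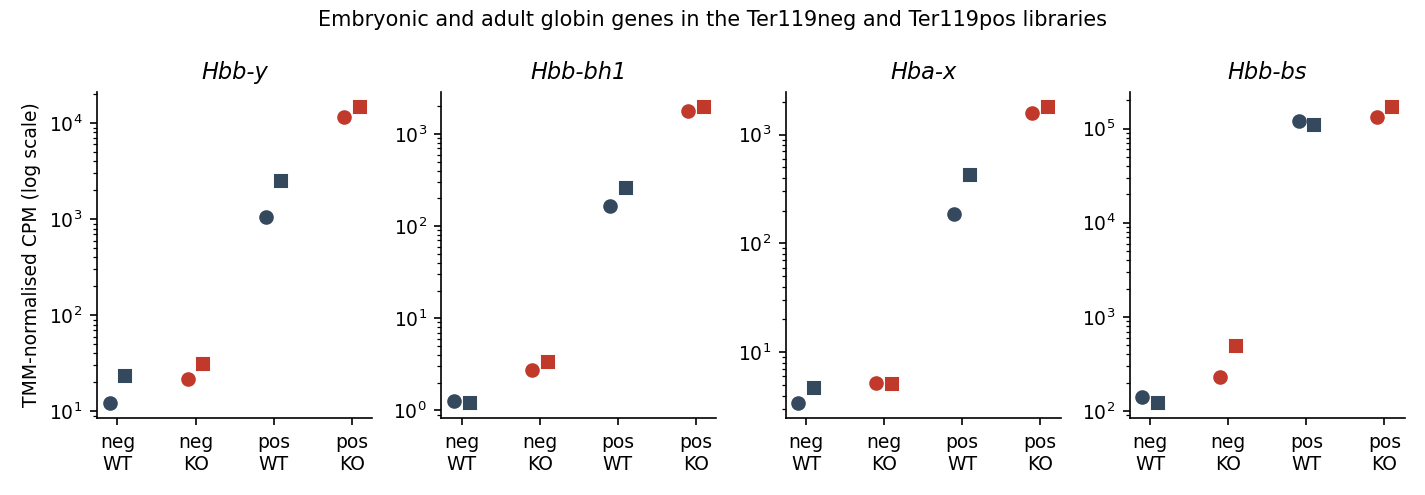
Level (TMM-normalised CPM, y axis on a log scale) of the embryonic globins Hbb-y, Hbb-bh1 and Hba-x and the adult Hbb-bs in each fetal liver library, by fraction and genotype, with circles and squares for letters A and B. Hbb-bh1 stood at 1870 CPM in Ter119pos KO and 212 CPM in Ter119pos WT.

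Immediate early and heat shock genes had 9 of 15 higher and 2 lower, the same over the list alone (median 1.36, adjusted p = 0.00633, 0.293 with an estimated correlation). Jun stood at 4.97, Junb at 4.31 and the mRNA-decay factor Zfp36 at 4.21. Members of 3 lists of other cell types were higher in part. They were 9 of 19 megakaryocyte genes with 2 lower (adjusted p = 0.0154, 0.469 with an estimated correlation), such as Plek (2.48) and Pf4 (1.92), and 9 of 20 endothelial and stromal genes with 2 lower (adjusted p = 0.0133, 0.516 with an estimated correlation), such as the angiopoietin receptor Tek (6.28). Of 24 hepatoblast genes 10 were higher (adjusted p = 0.00683, 0.816 with an estimated correlation). Over the list alone these counts were 9 and 2, 9 and 2, and 8, and 5, 4, 5 and 3 hepatoblast genes were higher without KO A, KO B, WT A and WT B. No endothelial gene was lower without KO A, KO B or WT A. Mitochondrially encoded genes had 9 of 13 higher, 10 over the list alone (adjusted p = 0.0144, 0.764 with an estimated correlation); 4 were higher without KO library B, and with the length trend removed 2 were higher and 4 lower (camera adjusted p = 0.907). Other called genes were the cytokine receptor subunit Csf2rb (3.66), which has the near copy Csf2rb2, the kinase Jak2 (-1.96), the heme oxygenase Hmox1 (4.08), Ddit4 (6.10), Prmt1 (1.08), Prmt2 (2.77) and Carm1 (-0.89). The remaining lists did not pass camera. Members higher and lower were 17 and 7 of 43 spliceosomal core proteins (adjusted p = 0.147), 4 and 15 of 39 interferon response genes (0.0583), 1 and 9 of 25 granulocyte and monocyte genes (0.114). They were 2 and 5 of 17 macrophage genes (0.784), 6 and 5 of 32 stem and progenitor genes (0.558), and 14 and 9 of 46 ribosome biogenesis genes (0.337). They were 3 and 5 of 13 end joining genes (0.733), 11 and 8 of 32 integrated stress response genes (0.363), 10 and 5 of 25 proapoptotic genes (0.126). For others they were 2 and 4 of 10 antiapoptotic genes (0.542), 5 and 4 of 23 cholesterol synthesis genes (0.657), and 9 and 7 of 26 cytokine receptor genes (0.611). They were 1 and 6 of 14 heme synthesis genes (0.199), 1 and 3 of 14 lymphoid genes (0.457), 0 and 2 of 13 mast cell genes (0.879), 4 and 3 of 12 arginine methyltransferase genes (0.633) and 1 and 1 of 5 sex-linked genes (0.638). With 1 library left out, lower counts became 4 for spliceosomal core proteins (WT B), 8 for interferon (WT A), 5 for granulocyte (KO A or WT A), 3 and 2 for macrophage (KO A and WT A), 2 and 3 for stem (KO A and WT B), 5 for ribosome biogenesis (WT B), 3 for proapoptotic (WT A) and 1 for lymphoid genes (WT A). The 14 higher ribosome biogenesis genes became 9 and 7 (KO B and WT A), and counts of 1 or 2 members moved by at most 2.

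Each of the 48 named genes called here kept its call when any library was left out, with 7056 to 7774 genes called. Removing the length trend left 8145 genes called, 7399 of them shared with the 8430. More genes were higher than lower with globin genes removed (4292 and 4136), with protein-coding genes alone (3537 and 3493) and in a model of this fraction alone (3987 and 3672).

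**Figure D4:**
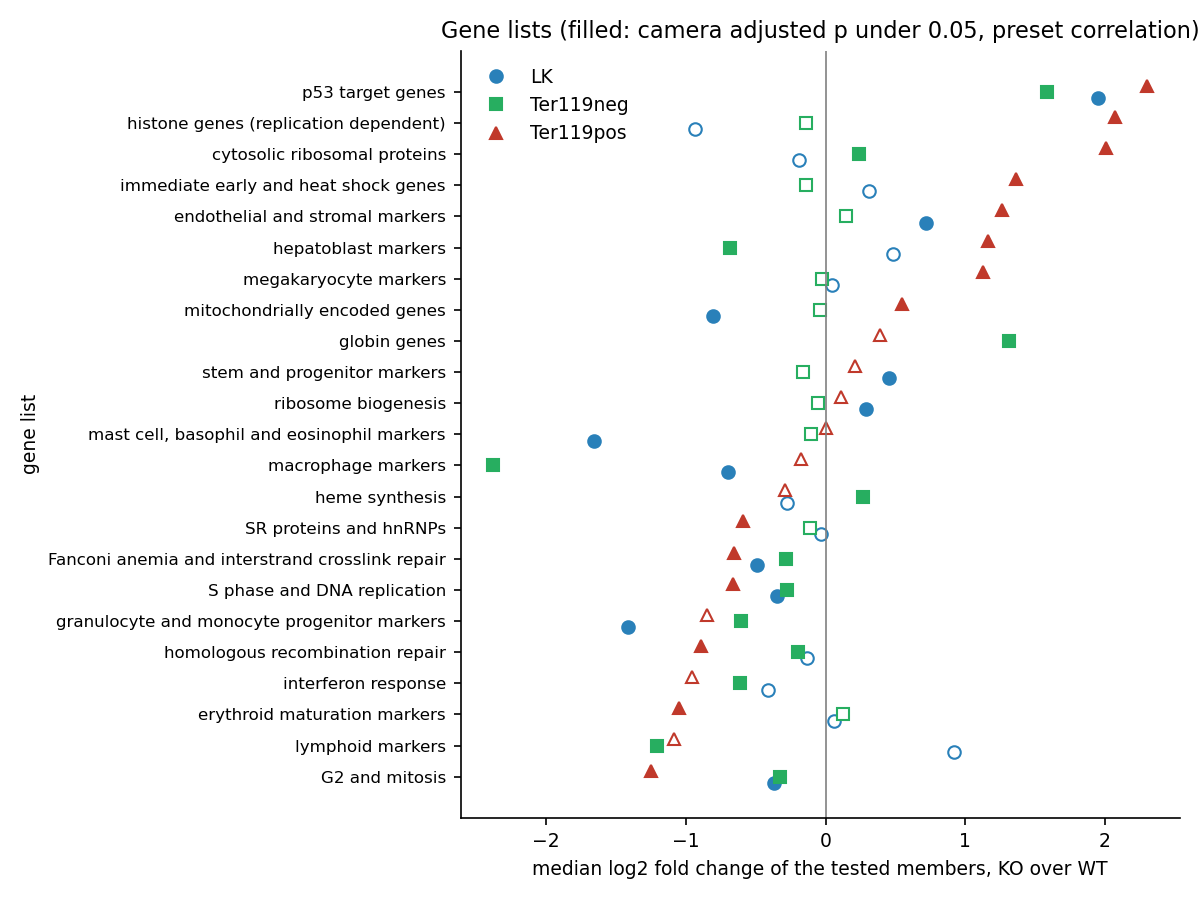
Median log2 fold change of KO over WT (x axis) of the tested members of each gene list (y axis) that passed camera in at least 1 population, for LK (circles), Ter119neg (squares) and Ter119pos (triangles). Filled symbols mark a camera adjusted p under 0.05 with the preset correlation. The p53 list has medians of 1.95, 1.58 and 2.30, and the G2 and mitosis list -0.37, -0.32 and -1.25.

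Whether the KO effect differed between the fractions was tested as an interaction, in which a positive log2 value means a more positive KO effect in Ter119pos than in Ter119neg. Of 15566 genes, 6491 differed, 3001 with positive and 3490 with negative values. This balance turned to 3533 and 2958 with globin genes removed, 2883 and 2689 with protein-coding genes alone and 3424 and 3288 without the low count filter, and without any 1 Ter119neg library to 2953 to 3170 positive and 2275 to 2384 negative. Ribosomal protein genes (78 of 78 positive, median 1.77, camera adjusted p = 6.49e-25) and histone genes (49 positive and 1 negative of 51, median 2.15, adjusted p = 1.49e-13) moved more upward in Ter119pos. Mitosis genes (37 of 42 negative, median -1.08, adjusted p = 1.78e-12), erythroid maturation genes (23 negative and 1 positive of 31, median -1.31, adjusted p = 2.45e-08) and homologous recombination genes (26 negative and 2 positive of 36, median -0.73, adjusted p = 2.57e-05) moved more downward. With an estimated correlation none of these 5 lists passed (adjusted p from 0.192 to 0.487). Prmt5 itself differed (1.67, SE 0.236, adjusted p = 0.000174), with a WT level of 15.7 CPM in Ter119pos and 52 CPM in Ter119neg.

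A further 10 lists passed camera, and none of them did with an estimated correlation (adjusted p from 0.339 to 0.664). The p53 list had 19 positive and 4 negative members of 40 (median 0.91, adjusted p = 0.00966). Perp, a p53-induced membrane protein, stood at 3.60 and Sesn1, a sestrin, at -1.14. Macrophage markers, lower in Ter119neg KO, had 13 positive and 1 negative of 17 (median 2.47, adjusted p = 2.85e-05). Hmox1 stood at 5.50, C1qc at 3.13 and Lgmn at 2.66. Hepatoblast genes (14 of 24 positive, adjusted p = 0.000128) and endothelial genes (7 of 20 positive, adjusted p = 0.00292; Tek 5.49) also differed. So did immediate early genes (8 positive and 2 negative of 15, adjusted p = 0.00245; Zfp36 4.37), megakaryocyte genes (8 positive and 1 negative of 19, adjusted p = 0.0192) and mitochondrially encoded genes (5 of 13 positive, adjusted p = 0.0192). With the length trend removed the median of the last list went from 0.59 to 0.20 and its call ended (adjusted p = 0.682). SR proteins and hnRNPs (18 negative and 1 positive of 32, adjusted p = 0.00058), replication genes (19 negative and 3 positive of 45, adjusted p = 0.00583) and heme synthesis genes (7 negative and 1 positive of 14, adjusted p = 0.02) went the other way. Adjusted over the list alone, the numbers of positive and negative members were 78 and 0 (ribosomal proteins), 49 and 1 (histones), 0 and 37 (mitosis), 1 and 23 (erythroid), 3 and 27 (recombination), 19 and 5 (p53), 14 and 1 (macrophage), 15 and 0 (hepatoblast), and 3 and 20 (replication).

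Among the genes picked by the naming rule, the highest interaction values were those of Anxa8, whose fitted value of 8.21 rests on WT counts of 0, and Rnu3b4 (7.62, SE 1.281). Among list members Csf2rb stood at 5.08, Rps14 at 2.73 and Hist1h3g at 2.71. Among the lowest were Cadm3 (-3.84, SE 0.511), the apolipoprotein L gene Apol8 (-3.61) and Ube2d2b (-3.47). Cenpe stood at -2.22 and Brca1 at -1.64.

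The mouse block takes up the single libraries of mice 3 and 5, so its WT difference between fractions comes from mouse 4 alone. The spread between mice is then judged from mice 1 and 2 only. With mouse as a block, 6250 genes differed, and Anxa8 lost its call (3.02, adjusted p = 1). Heme synthesis no longer passed camera (adjusted p = 0.0613). The interferon list did pass it (0.0386 against 0.968, and 0.732 with an estimated correlation under the block). Mitochondrially encoded genes had 10 positive members. Without the Ter119neg libraries KO A, KO B and WT A, 17, 17 and 16 recombination genes were negative, and without KO A, KO B, WT A and WT B, 9, 8, 8 and 9 SR protein and hnRNP genes. Without KO B, WT A and WT B of Ter119neg, 12, 12 and 11 replication genes were negative, and without KO B 4 heme genes. Without the Ter119pos library KO B, 0 replication genes were positive. Without the Ter119pos libraries KO A, KO B, WT A and WT B, 9, 8, 9 and 7 hepatoblast genes were positive, and 10, 2 and 3 mitochondrially encoded genes without KO A, KO B and WT A (8 without Ter119neg WT A). Anxa8 lost its call without the Ter119neg WT library A.

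Ter119pos was compared with Ter119neg in WT mice to describe the difference between fractions beside which the KO effects stand. Ter119neg libraries also held transcripts of granulocyte, hepatoblast and other cell types, so the comparison mixes erythroid maturation with cell types. Erythroid genes were higher in Ter119pos: 31 of 31 maturation genes (median 5.09), 14 of 14 heme synthesis genes (median 3.99) and 9 of 9 globin genes (median 9.22). Cell cycle genes were higher too, with 42 of 42 mitosis genes and 38 of 45 replication genes (4 lower), as were 27 of 36 recombination genes (1 lower). Stem and progenitor genes were lower in 29 of 32 cases (2 higher), and so were all 25 granulocyte and monocyte genes, all 24 hepatoblast genes and 42 of 46 ribosome biogenesis genes (1 higher). In all, 11876 of 15566 genes were called, 5584 higher and 6292 lower.

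Among the genes picked by the naming rule, with Hist2h3c1 set aside because it stood at 0 in both Ter119neg WT libraries, the highest log2 fold changes were those of Fn3k (10.15, SE 0.238), a kinase acting on fructosamine, Hbb-bs (9.77), Alas2 (9.68), Hbb-bt (9.56), Hba-a2 (9.36), whose near copy is Hba-a1, Apol11b (9.30) and Slc4a1 (9.30), with adjusted p values from 5.22e-11 to 2.54e-09. Hbb-bs reached 115000 ± 8700 CPM against 131 ± 14 (SD, n = 2 each). Among the lowest were the eosinophil genes Ear1 (-7.60, SE 0.503), Epx (-5.84), Prg2 (-5.47) and Ear6 (-5.31), and Ramp1 (-4.75), a receptor activity modifying protein. Among list members, the erythroid genes Trim10 (7.71) and Hemgn (5.91), the phosphatase Cdc25b (6.58), the antiapoptotic Bcl2l1 (6.15), the E2F family transcription factor E2f2 (6.06), the mitotic kinesin Kif23 (2.75) and Brca1 (2.70) were higher. Cd34 (-4.08), the receptor Kit (-3.71) and the transcription factors Myb (-3.50) and Myc (-3.10) were lower. Prmt5 was lower in Ter119pos (-1.72, SE 0.138, adjusted p = 1.99e-07), and so were its cofactors Wdr77 (-1.33) and Clns1a (-1.22) and the methyltransferases Prmt1 (-2.17) and Prmt7 (-1.64).

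Camera adjusted p values were 7.12e-15 (erythroid), 3.22e-08 (heme), 6.17e-06 (globin), 1.35e-13 (mitosis), 6.08e-07 (replication), 3.01e-05 (recombination), 4.24e-06 (stem), 3.55e-06 (granulocyte), 1.34e-05 (hepatoblast) and 1.81e-07 (ribosome biogenesis), and 0.1 to 0.555 with an estimated correlation. Adjusted over the list alone the counts were the same except for 28 higher recombination genes. In KO mice the same comparison called 9746 genes, 4719 higher and 5027 lower in Ter119pos, with 30 of 31 erythroid maturation genes, 31 of 42 mitosis genes, all 78 ribosomal protein genes and 49 of 51 histone genes higher, and Prmt5 was not called (-0.05, adjusted p = 0.834). More genes were higher than lower in WT with the length (6080 and 5744) or GC trend (5937 and 5685) removed and with length removed under the mouse block (5599 and 4583). In KO this was so, with 50.5 to 56.2% higher, for these 3, RLE, DESeq2, globins removed, protein-coding genes alone and without Ter119neg KO A or B or Ter119pos KO A.

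The calls of the 3 KO comparisons were set against each other to see which genes they shared. LK and Ter119neg, which share no mice, had 113 genes higher in both, where independent lists would share 14.3, 58 lower in both against 9.22, and 0 in opposite directions against 24.6, among 13042 genes tested in both. LK and Ter119pos had 108 higher in both (40.3 for independent lists), 34 lower in both (24.9) and 12 opposite (67.4). Ter119neg and Ter119pos had 900 higher in both (370), 676 lower in both (436) and 361 opposite (806), but mice 1, 2 and 4 gave both fractions, so these are not independent. Across genes, which are not independent replicates, Pearson correlations of the log2 fold changes were 0.557, 0.161 and 0.308, and Spearman correlations 0.48, -0.009 and 0.246. With the LK letter block the genes called in both LK and Ter119neg were 493 higher (119 for independent lists) and 644 lower (183), with 52 opposite (296), and those in both LK and Ter119pos were 430 higher (336), 453 lower (485) and 661 opposite (809). Higher in all 3 comparisons were 96 genes, 17 of them on the p53 list, and lower in all 3 were 26, Prmt5 among them.

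**Figure D5:**
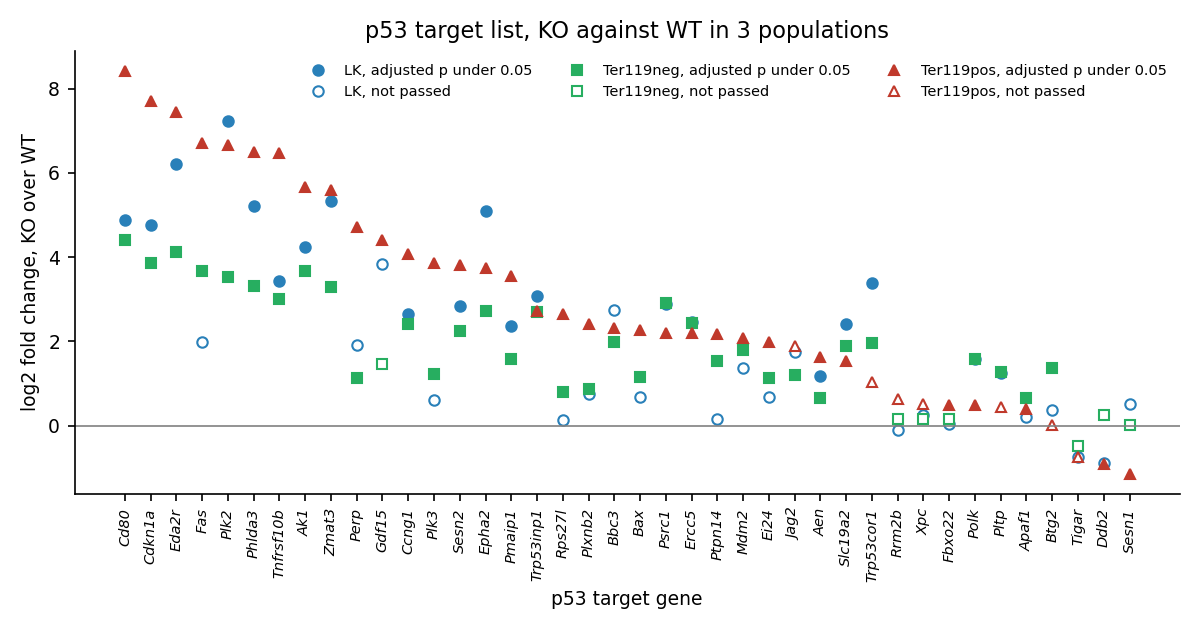
Log2 fold change of KO over WT (y axis) of each of the 40 p53 target genes (x axis, ordered by the Ter119pos value) in LK (circles), Ter119neg (squares) and Ter119pos (triangles), filled where the edgeR adjusted p was under 0.05. Cdkn1a has values of 4.77, 3.87 and 7.70, and Sesn1 lies below 0 in Ter119pos alone, at -1.14.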

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

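The tests on composition, on embryonic globins and on the share of other cell types were chosen after the results were seen, as were the alternatives with protein-coding genes alone; those on transcript length of gene lists had their predictions written before.

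A tested difference of the KO effect between Ter119pos and Ter119neg singled out 6491 genes and 15 lists. Median interaction log2 values were 2.47 for macrophage markers, 2.15 for histone genes, 2 for immediate early genes, 1.83 for hepatoblast markers, 1.77 for ribosomal proteins, 1.46 for endothelial and stromal markers, 1.21 for megakaryocyte markers, 0.91 for p53 targets and 0.59 for mitochondrially encoded genes. They were -1.31 for erythroid maturation, -1.08 for G2 and mitosis, -0.73 for homologous recombination, -0.54 for heme synthesis, -0.46 for SR proteins and hnRNPs and -0.36 for S phase and DNA replication. With a correlation estimated from the data 0 of these lists passed.

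Named genes with a more positive KO effect in Ter119pos were Anxa8 (8.21), Rnu3b4 (7.62), Tubb3 (6.71), Prrg4 (6.04), Hmox1 (5.50), Tek (5.49), Vgf (5.23), Csf2rb (5.08), Zfp36 (4.37), Jun (4.19), Cd80 (4.02), Junb (4.00), Cdkn1a (3.83), Perp (3.60), Eda2r (3.32), C1qc (3.13), Plk2 (3.13), Ddit4 (3.02) and Rps14 (2.73). So were Hist1h3g (2.71), Lgmn (2.66), Plek (2.46), Ctss (2.44), Hbb-y (2.32), Prmt2 (2.13), Hba-x (2.10), Hbb-bh1 (1.83), Pf4 (1.75), Prmt5 (1.67), Cd5l (1.67), Ccng1 (1.66), Adgre1 (1.58), Sesn2 (1.57), Csf1r (1.51), Sdc3 (1.32), Bax (1.12), Cd34 (0.92), Morf4l2 (0.73) and Prmt1 (0.66). Anxa8 rests on Ter119pos WT counts of 0, and with mouse as a block it was not called (3.02). Prrg4 also stood at 0 CPM in both Ter119pos WT libraries, and at 4.34 and 4.57 CPM in KO. Its fitted value of 6.04 thus rests on counts of 0 too and is not a lower bound. Ter119neg WT library A stood above WT library B for several genes, such as Eda2r (1.95 and 0.119 CPM), Cdkn1a (5.66 and 1.29), Cd80 (0.584 and 0.0477) and Plk2 (1.87 and 0.692). The higher level in library A makes their interaction values larger, and values for them without that library are not given here. Named genes with a more negative effect were Cadm3 (-3.84), Apol8 (-3.61), Ube2d2b (-3.47), Aim2 (-3.29), Angpt2 (-2.94), Aqp1 (-2.55), Hbq1b (-2.32), Mki67 (-2.23), Cenpe (-2.22), Cenpf (-2.16), Brd8 (-2.11), Alas2 (-1.89), Clspn (-1.69), Brca1 (-1.64) and Jak2 (-1.59). So were Gen1 (-1.38), Fancm (-1.34), Epc1 (-1.34), Epc2 (-1.33), Brca2 (-1.31), Top2a (-1.28), Pola1 (-1.26), Sesn1 (-1.14), Hnrnpm (-1.11), Ep400 (-1.09), Prpf3 (-0.54) and Carm1 (-0.50).

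In 7 named genes every KO library lay beyond every WT library in LK and on the opposite side in a fetal fraction, a difference between tissues that was not tested. The LK log2 fold changes were -2.72 for H2-Aa, 0.31 for Epc1, -0.69 for Zfp36, -0.92 for Csf2rb, 1.36 for Apol8 and -2.13 for Epx, against Ter119pos values of 0.63, -1.18, 4.21, 3.66, -0.95 and 1.05. For Slc4a1 it was -5.31 against 0.28 in Ter119neg. Some of these differences are small or near the floor. In Ter119pos KO and WT, H2-Aa stood at 0.21 and 0.259 against 0.18 and 0.118 CPM. Epx there stood at 0.49 and 0.776 against 0.361 and 0.235 CPM. Slc4a1 in Ter119neg stood at 22.4 and 27.5 against 20.6 and 20.5 CPM. For Epc1 the lowest LK KO library had 39.2 CPM and the highest LK WT library 39.1 CPM. With 2 libraries per group such separation can easily arise without a change.

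The ribosomal protein, histone, mitosis and recombination groups in Ter119pos were weighed against a length trend, and the ribosomal protein and mitosis groups also against a few genes taking most counts. With the length trend removed the medians were 1.562 (2.006 before, standard error over members 0.052), 1.33 (2.074, 0.278), -1.244 (-1.253, 0.084) and -0.875 (-0.893, 0.104), each list still passing camera. The trend on the longest annotated transcript is thus not the whole source of the mitosis and recombination changes. It could carry part or more of the histone and ribosomal protein change. The removal cannot decide how much, since a gene measured through a shorter transcript would be corrected too little. Normalised over protein-coding genes, which leaves out the structural RNAs, the ribosomal protein median was 2.055 (0.046) and the mitosis median -1.196 (0.099). That step keeps protein-coding globin genes, and globin genes took 16.4 to 25.1% of counts in the Ter119pos libraries. It therefore does not weigh the globin share. A biological change of maturation stage or cycle remains a hypothesis, and library differences that move with genotype stay open.

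The embryonic globins in Ter119pos KO were weighed against the length trend and a changed cell mixture. Hbb-y lay above the adult Hbb-bs by 2.504 (SE 0.524), although their transcripts are of similar length, so length alone does not account for it. The widest gap among Hbb-y, Hbb-bh1 and Hba-x was 1.87 standard errors of the difference. Those errors treat the 3 genes as independent, although they were measured in the same libraries. In Ter119pos WT libraries A and B, Hbb-y stood at 1050 and 2500 CPM and Hba-x at 187 and 428 CPM. The gap therefore cannot decide whether the 3 genes rose by 1 common factor, as a larger share of primitive erythroid cells would give. The Ter119 gate does not remove these cells. Hbb-y stood at 13200 CPM in KO and 1770 CPM in WT. All 3 genes are on the globin list, and higher expression per cell was not tested.

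The macrophage markers in Ter119neg KO were weighed against a lower share of every other cell type and a length trend. The megakaryocyte median lay above the macrophage median by 2.357 (standard error over members 0.268), so the 2 lists moved apart in these libraries. That error treats the members as independent, although they were measured in the same libraries. Medians were -0.02 for megakaryocyte, -0.10 for mast cell and 0.15 for endothelial markers, with members going both ways, and -0.61 for granulocyte and monocyte, -0.68 for hepatoblast and -1.21 for lymphoid markers, against -2.38 for macrophages. With the length trend removed the macrophage median was -2.379 (-2.38 before, 0.233). Fewer macrophages, or lower expression in them, could each give these values, and nothing here separates them; Csf1r, at 16.9 CPM in KO and 53.7 CPM in WT, is also on the granulocyte and monocyte list.

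The 10 splits of the 6 LK libraries, and the 4 that part all letter pairs, are too few for a share under 0.05. Of the 10 splits 1, the real one, gave as many genes, 250 against at most 0 in the others, and 1 as many p53 targets, 18 against at most 0. Of the 4 splits under the letter block 1 gave as many, 3129 against at most 0.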

How the results depend on the processing

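The alternatives with length or GC trends removed, length removal with a block, protein-coding genes alone and both letter B or C libraries left out were chosen after the data were seen.

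Counts of called genes in LK moved from 250 to 963 with DESeq2, 3129 with the letter as replicate block, 474 with length and 450 with GC removed, 3747 with length removed under the block, 71 without both B and 14 without both C libraries. They were 33 to 268 with 1 library left out, and 1450 to 1788 in Ter119neg, against 2976; fewer libraries were used there, and elsewhere the cause was not tested. Counts of the other 4 comparisons stayed within 1.5 times under each alternative run. Prmt5 in LK kept its direction (log2 -2.97 to -2.48) and lost its call without KO library A, B or C and, at -2.826 (adjusted p = 0.0965), without both C libraries, over a range of 3.12e-14 to 0.0965.

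With an estimated correlation the lists past the test fell from 11 to 1 in LK (0 under the block) and from 13, 14, 15, 18 and 18 to 0 in Ter119neg, Ter119pos, the interaction and the WT and KO fraction comparisons, there also 0 under the mouse block. With fry 1, 9, 20, 15, 24 and 26 lists passed in LK and these 5, and with length removed 11, 13, 13, 14, 17 and 16 of those past camera kept the call. Genes called the same way in LK and Ter119neg became 413 with DESeq2 and 1137 with the block, and in LK and Ter119pos 324 and 883; the cause was not tested. Of named gene results, 1191 kept their status, called or not, under the alternatives fixed in advance, 13 lost a call and 1 gained one. With 1 library left out 704 kept their status and 102 lost a call. Under added alternatives 595 kept their status and 40 lost a call. No called gene reversed. Without a call in any of these fits, Hbb-bt in Ter119pos reversed from 0.413 to -0.232 with length removed, and Prmt5 between fractions in KO from -0.049 to 0.009 with RLE, 0.073 with globins removed, 0.102 with protein-coding genes alone, 0.142 with length (0.141 under the mouse block) and 0.182 with GC removed; it was -0.272 to 0.156 with 1 library left out. All 32 named LK genes kept their call under the letter block.

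The median over all genes moved by over 0.1 with globins removed (interaction -0.005 to 0.128, fractions in KO -0.118 to 0.009), without a Ter119neg library (interaction to 0.133 to 0.166, fractions in KO to -0.007 without KO A), without the low count filter (fractions in WT -0.193 to -0.344), with protein-coding genes alone (Ter119pos -0.042 to 0.067, interaction to 0.111), with length removed (fractions in WT to -0.046, in KO to 0.018; 0.012 and 0.018 under the mouse block) and with GC removed (-0.03 and 0.019). Of 100 simulated 2-fold changes 0 were recovered in LK, 61 in Ter119neg and 59 in Ter119pos, so a missing call does not exclude a change of that size. The simulation drew libraries independently, with spreads estimated without the letter block. The LK recovery therefore does not describe the fit with that block. Why fewer were recovered in LK was not tested.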

Other observations

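The genes below were chosen after their values were seen, from those called in all 3 KO comparisons.

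Tert, the reverse transcriptase of telomerase, was higher in KO, with log2 fold changes of 2.5 in LK, 2.07 in Ter119neg and 3.51 in Ter119pos. The D-type cyclin Ccnd2 was higher by 1.41, 0.69 and 3.14, and the receptor Notch3 by 4.60, 2.42 and 0.68. Taf15, an RNA-binding protein of the FET family, was lower, at -1.84, -1.48 and -1.62. The fatty acid receptor Cd36 stood at -2.63, -1.63 and -2.72, the desaturase Scd1 at -3.07, -0.82 and -0.53, the red cell pyruvate kinase Pklr at -1.67, -1.69 and -0.66 and the lamin Lmnb2 at -1.21, -0.96 and -1.11.

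Both LK libraries of letter C held Xist, at 773.7 CPM in WT and 335.9 CPM in KO, beside the Y-linked Ddx3y at 32.33 and 59.35 CPM, while the other 4 LK libraries had 0.05411 to 0.6692 CPM of Xist. The neutrophil gene S100a9 was at 9643 and 2020 CPM in the same libraries. Mouse 2 had 371.7 and 462.2 CPM of Xist in its Ter119neg and Ter119pos libraries and 0 CPM of Ddx3y in both.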
